A study of Mus musculus with 8 samples.

How the data were processed

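RNA sequencing of 8 libraries from MC3T3-E1, a mouse line of calvarial pre-osteoblasts that can be differentiated into osteoblasts in culture, was analysed from the count table of the whole series. Per the labels' protocols, RNA was harvested with Trizol and the libraries were made by a service provider with a protocol described as poly(A)-enriched/ribo-depleted, so the labels leave open which of these selections was used. Per the submitters' processing notes, FastQC 0.11.9, Trimmomatic 0.39, STAR 2.7.10a and featureCounts 2.0.3 were used, and the builds GRCh38 and GRCm38 are named. The gene symbols of the table are mouse symbols. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The deposited values are whole-number counts of reads per gene, not normalised, as the authors made them. The table holds 28901 genes, of which none was at 0 in every library.

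Groups were taken from the sample titles, which give 4 groups of 2 libraries called Brd, control, NM-Brdi and NM-DMSO. The design text of the series describes treatment with DMSO, the vehicle, or with I-BRD9, an inhibitor of the bromodomain protein BRD9, at 10 µM, and an osteogenic medium with dexamethasone at 0.1 µM, ascorbic acid and a glycerol phosphate. No label says which libraries received the osteogenic medium, what the Brd and control cultures received, or what the prefix NM stands for, so groups are called by their titles. Nothing in the labels says that the 2 libraries of a group came from separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical.

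Total counts ran from 16918182 to 24555028 per library. Levels are given as CPM, counts scaled to a common library size with TMM factors, and 1 CPM stood for 16.4 to 26.1 counts. Genes were kept with the filterByExpr function of edgeR 4.0.16, which left 17038 genes. Counts were scaled with TMM factors and fitted with edgeR's quasi-likelihood model (glmQLFit and glmQLFTest, R 4.3.3) in 1 fit of the 8 libraries with 1 term per group. Adjusted p-values are Benjamini-Hochberg values over the tested genes, and a gene was called when its value was under 0.05. Fold changes are the fitted log2 ratios, each with its standard error (SE) derived from the quasi-likelihood F statistic. The comparisons were Brd against control, NM-Brdi against NM-DMSO, the difference of these differences (the interaction), and control against NM-DMSO. The biological coefficient of variation of the fit was 0.148.

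A total of 29 gene lists were fixed before the data were examined, and 26 of them had at least 3 tested members. The lists of endothelial, epithelial and skeletal muscle markers had fewer and were not tested. Of the 497 listed genes, 27 were not in the table and 15 were found through a synonym. Lists were tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01, and again with a correlation estimated from the data. Camera asks whether the genes of a list moved more in a direction than other genes, and its p-values were adjusted over the lists of a comparison. Named genes followed a rule fixed before the data were examined. The rule takes 10 genes of osteoblast and BRD9 interest whatever their result. It adds up to 10 genes higher and 10 lower with the largest called change, a mean of at least 10 CPM and no overlap between the libraries of the groups (5 and 5 for the interaction, without the overlap condition). It also adds the 4 members with the smallest p of each list called by camera and up to 3 called members of other lists. Clone-based and predicted names were left out.

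Gene identifiers and positions are those of GENCODE M21 on GRCm38, to which 96.9% of the symbols were matched. This annotation was not stated to be the one used for counting. Longest transcripts of the named genes were aligned with BLAST+ 2.17.0 to all transcripts of that annotation. Alignments of at least 200 nt at 95% identity to another gene of the table marked genes whose reads could be shared. Bglap shared 439 nt with Bglap2, and Bglap2, Bnip3, Idi1, Glul, Smarcc1, Ak4, Ifit3 and mt-Nd3 matched copies elsewhere, so their values are uncertain. Msmo1 matched other genes over at most 203 of 2969 nt, and Mki67 matched Gm44521 over 216 of 10061 nt. Reads of these short stretches could be shared. Fosl1, Csf1r, Tagln, Ccna2, Cebpb, Smpd3 and Gas2 overlapped exons of neighbouring genes with counts of their own, and are uncertain because the strand setting is not given. Ctnnb1, Runx2, Jun, Gas1, Sfrp2, Tgfb3 and Itga10 overlapped genes with far fewer counts. Processed pseudogenes held 14.8% to 21.2% of the counts of a library.

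The model was tested on simulated counts with 200 changed genes. For Brd against control, over 16641 genes, it recovered 77.1% of the genes changed 2-fold and 96.9% of those changed 4-fold, but 11 of the 65 changed 1.5-fold. For NM-Brdi against NM-DMSO, over 16639 genes, the shares were 75.7%, 100% and 12.7%. Of the calls, 2.3% and 4.5% were false. The simulation gave all groups the same spread, unlike these data, where the NM-DMSO libraries varied more than the others. These rates may therefore not hold here, above all for NM-Brdi against NM-DMSO.

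Alternatives fixed before the data were examined were DESeq2 size factors, no filter on low counts, the replicate number as a block, each library left out in turn, only the 4 libraries of a comparison, the DESeq2 1.42.0 Wald test, and the estimated correlation. A transcript length correction and limma voom with quality weights for the libraries were added after the data were seen. Where a group had 1 library left, it was assumed to vary like the others. Where a group had at most 3 counts, the ratio of pooled counts replaced the fitted fold. It was computed against a floor of 3 counts over the group when the group had none, and otherwise given with a 95% interval. Floors and intervals cover counting error only. Figures were drawn with matplotlib 3.10.9.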

Results

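The transcriptome of MC3T3-E1 cells, a mouse pre-osteoblast line, was measured by RNA sequencing in 4 groups of 2 libraries titled Brd, control, NM-Brdi and NM-DMSO. The series asks how the bromodomain protein BRD9 and Wnt/β-catenin signalling bear on Sp7, a transcription factor required for osteoblast differentiation. Total counts were 16918182 and 18069126 in Brd, 19945266 and 17311252 in control, 24555028 and 23688093 in NM-Brdi, and 20980664 and 21636493 in NM-DMSO. The first principal component held 53.8% of the variance and parted the groups with the prefix NM from the others. The NM-DMSO libraries differed from each other more than those of any other group. In that group 566 genes were over 2-fold apart, against 0 in Brd, 0 in control and 2 in NM-Brdi. The fit takes a shared spread per gene for all groups, although NM-DMSO varied more. Its p-values may be too small in comparisons with NM-DMSO and too large in Brd against control. Counts of called genes are therefore also given without NM-DMSO replicate 1, which lay farther from the other libraries on that component (91.1, against 28.4 for replicate 2). Such a fit takes no spread from NM-DMSO, so its counts are no safer for comparisons with that group. Processed pseudogenes held 21.2% of the counts of replicate 1 and 18.0% of those of replicate 2. The share was 17.3% to 17.4% in NM-Brdi and 14.8% to 15.2% in Brd and control. It therefore differed with the prefix NM, and so between control and NM-DMSO.

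**Figure D1:**
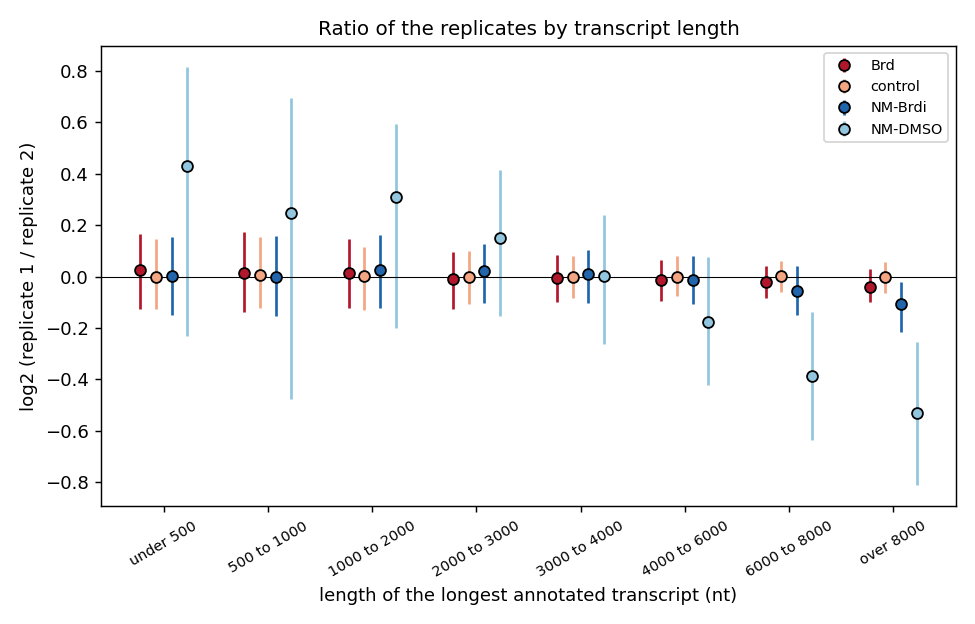
Median log2 ratio of replicate 1 to replicate 2 (y axis) of genes binned by the length of the longest annotated transcript (x axis, nt); points are medians of the genes of a bin and bars span the quartiles. In NM-DMSO the median was 0.43 in the shortest bin and -0.53 in the longest.

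Sp7, Runx2, Alpl, Ibsp, Spp1 and Axin2 were lower in Brd than in control. Sp7 (chromosome 15, 102356606 to 102367182, GRCm38) stood at 192 ± 13.1 CPM in Brd and 405 ± 10.3 CPM in control (mean ± SD, n = 2), a log2 fold change of -1.08 (SE 0.15, adjusted p = 0.00698). Runx2, the other master regulator of osteoblasts (chromosome 17, 44495987 to 44814797), fell by 0.66 on the log2 scale (SE 0.13, adjusted p = 0.0264). Alpl, the tissue-nonspecific alkaline phosphatase, was 4.63-fold lower (adjusted p = 0.00221). Ibsp and Spp1, which encode the bone matrix sialoproteins, were 3.95-fold and 3.86-fold lower (adjusted p = 0.013 and 0.00135). Axin2, a feedback target of β-catenin, was 2.52-fold lower (adjusted p = 0.00412). Brd9 itself (chromosome 13, 73937811 to 73960895) had 24.1 ± 0.0701 CPM in Brd and 30.1 ± 1.33 CPM in control and did not pass the test (log2 fold change -0.32, adjusted p = 0.13), although it did without either NM-DMSO library (adjusted p = 0.0053 without replicate 1). Ctnnb1, which encodes β-catenin (log2 fold change -0.09), Col1a1 (-0.06) and Bglap (-0.70), whose reads may be shared with Bglap2, did not pass it either.

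Of the genes that the naming rule takes by size, which are called and have at least 10 CPM in the group with the higher level, Lum, Vit and Dcn had the largest decreases. Lum and Dcn encode the small leucine-rich proteoglycans lumican and decorin. Lum went from 566 ± 13.2 CPM in control to 16.1 ± 3.75 CPM in Brd, and Dcn, at 265 ± 3.71 CPM in control, was 15.7-fold lower in Brd (adjusted p = 0.000488). Vit, Astn1, Ikzf4, Mettl21e, Hp, Tnr, H19 and Ecrg4 were 10.9-fold to 25.2-fold lower. Among the genes the rule takes as higher, the largest increases were in Creb5, a transcription factor of the CREB family (11.6-fold), and Ccn2, which encodes connective tissue growth factor (9.31-fold). Mcam, Cemip, Sema3c, Elovl7, Sort1, Slc45a3, Sema3f and Ankrd1 were 4.37-fold to 8.52-fold higher.

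**Figure D2:**
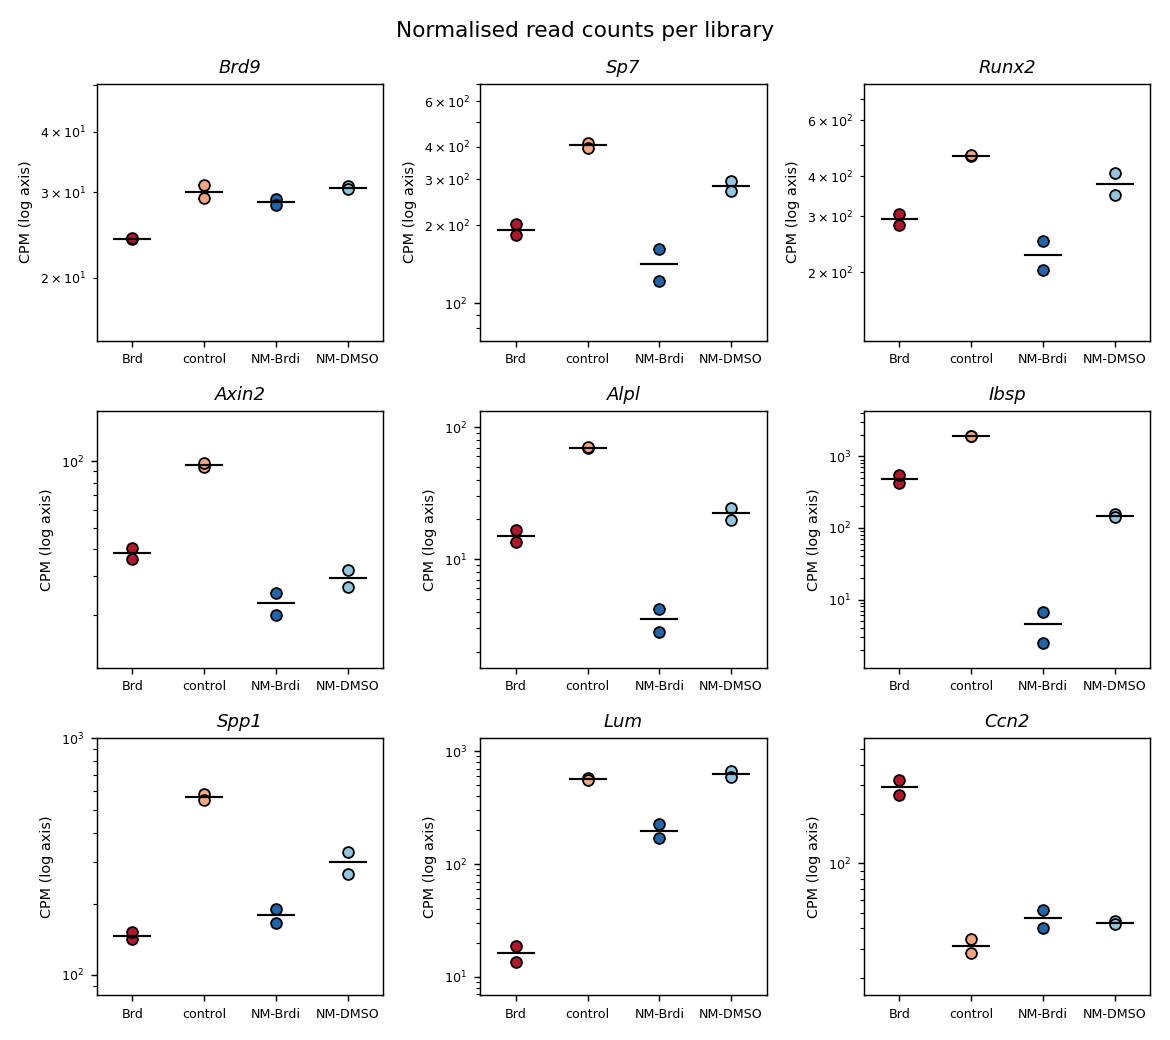
Normalised read counts (CPM, log axis) of 9 genes in the 8 libraries; each point is a library and each line the mean of a group of 2. Sp7 was lower in both Brd libraries than in both control libraries, and lower in both NM-Brdi libraries than in both NM-DMSO libraries.

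Among the fixed lists, cell cycle genes were lower as a group in Brd. All 30 had a negative fold change (median -0.60), and 16 were called lower, or 25 adjusted over the list alone (camera adjusted p = 1.13e-17; adjusted p = 0.0941 with an estimated correlation). Plk1 and Cdc20, regulators of mitosis, fell by 1.03 and 1.05 on the log2 scale. Camera called the following lists lower as well. Of 15 osteoblast transcription factors, 7 were called lower and 0 higher, 8 and 0 adjusted over the list alone (adjusted p = 0.0982 with an estimated correlation). Of 26 genes of bone matrix and mineralization, 7 were lower and 1 higher, 11 and 2 adjusted over the list alone (adjusted p = 0.178 with an estimated correlation). Of 16 Wnt/β-catenin target genes, 6 were lower and 1 higher, 8 and 1 adjusted over the list alone (adjusted p = 0.135 with an estimated correlation). Besides Axin2 these included Rnf43 (-1.25), Tnfrsf19 (-1.45) and Tcf7 (-1.93). Of 8 chondrocyte markers, 2 were lower, 6 adjusted over the list alone (adjusted p = 0.0941 with an estimated correlation). Cyp1b1, Aldh3a1 and Ahrr were the 3 called of 5 aryl hydrocarbon receptor targets, all lower, and 3 adjusted over the list alone (adjusted p = 0.102 with an estimated correlation).

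Immediate early genes, the first transcripts induced by growth factors and stress, were on the higher side, and camera called them and the next 2 lists higher. All 13 had a positive fold change (median 0.81), and Jun, Ier3, Egr1 and Ier2 were called, 10 adjusted over the list alone (adjusted p = 0.0941 with an estimated correlation). In the BMP and TGF-β pathway, 5 of 26 genes were higher and 1 lower, 6 and 1 adjusted over the list alone (adjusted p = 0.196 with an estimated correlation). They included Ccn2. Of 17 hypoxia-response genes, 5 were higher, 7 adjusted over the list alone (adjusted p = 0.123 with an estimated correlation). They included Ndrg1 (0.99) and Car9 (1.69). Cholesterol and fatty acid synthesis genes (3 of 25 lower, 6 adjusted over the list alone) and NRF2 targets (2 of 13 lower, 7 adjusted over the list alone) were called lower by camera. Their adjusted p was 0.0941 and 0.257 with an estimated correlation. The lists of glucocorticoid targets, osteoclast-coupling factors and macrophage and osteoclast markers were called lower, and those of smooth muscle and replication-dependent histone genes higher. Of the glucocorticoid targets 4 of 17 were lower and 1, Sgk1 (0.53), was higher, 6 and 1 adjusted over the list alone. Of the osteoclast-coupling factors 1 of 4 was lower, 1 adjusted over the list alone. Of the macrophage and osteoclast markers 2 of 6 were lower and 0 higher, 3 and 1 adjusted over the list alone. Of the smooth muscle genes 1 of 8 was higher and 0 lower, 5 and 1 adjusted over the list alone, and of the histone genes 2 of 8 were higher, 2 adjusted over the list alone. The adjusted p of these 5 lists was 0.123, 0.185, 0.196, 0.284 and 0.284 with an estimated correlation. Leaving out 1 library ended the camera call of 4 of the 16 called lists. For osteoclast-coupling factors the adjusted p was 0.0642 at most, without a Brd or an NM-DMSO library. For smooth muscle genes it was 0.0827 without control replicate 1 and at most 0.0516 without an NM-Brdi library. For macrophage and osteoclast markers it was 0.0573 without Brd replicate 2 and at most 0.0828 without an NM-DMSO library. For histone genes it was 0.23 without Brd replicate 1.

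Altogether 1121 of 17038 genes were called between Brd and control, 533 higher and 588 lower, and 473 of them changed at least 2-fold. The share called higher was 47.5%, and it was smallest in the fits without a control library. Without NM-DMSO replicate 1, which enters only through the shared estimate of the spread, 5546 genes were called, 5505 without NM-DMSO replicate 2 and 6412 in a fit of the 4 libraries alone. The count was 34 without Brd replicate 1, 107 without Brd replicate 2, 59 and 60 without control replicates 1 and 2, and 609 and 604 without NM-Brdi replicates 1 and 2. In these 8 fits 12 of the 78 called genes that the naming rule takes stayed called throughout, among them Spp1, Lum, Dcn, Ccn2 and Creb5. Sp7, Runx2, Axin2 and Ibsp lost the call when any 1 of the 4 libraries of this pair was left out, and Alpl without Brd replicate 1. Over the 8 fits the log2 fold change ranged from -1.147 to -1.008 for Sp7 and from -0.718 to -0.603 for Runx2. It ranged from -1.418 to -1.251 for Axin2, from -2.166 to -1.817 for Ibsp and from -2.367 to -2.068 for Alpl.

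Ibsp, Alpl, Bglap, Sp7, Runx2 and Spp1 were lower in NM-Brdi than in NM-DMSO. Ibsp went from 148 ± 8.62 CPM in NM-DMSO to 4.56 ± 2.93 CPM in NM-Brdi (log2 fold change -5.03, SE 0.39, adjusted p = 0.00453). Alpl was 6.35-fold lower (adjusted p = 0.00453) and Bglap 3.55-fold lower (adjusted p = 0.0289). Sp7 stood at 142 ± 28.4 CPM against 283 ± 16.5 CPM (log2 fold change -0.99, SE 0.14, adjusted p = 0.0231). Runx2 and Spp1 fell by 0.74 and 0.74 on the log2 scale (adjusted p = 0.041 and 0.0418). Brd9 (-0.10), Ctnnb1 (0.02), Axin2 (-0.38) and Col1a1 (-0.50) did not pass the test. Over the fits without 1 library the log2 fold change ranged from -0.563 to -0.22 for Axin2 and from -0.577 to -0.405 for Col1a1. Fits without an NM-DMSO library take no spread from that group, the most variable, so their p-values do not settle these genes.

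The list of bone matrix and mineralization had 11 of 26 genes lower, 19 adjusted over the list alone, and 0 higher, 1 adjusted over the list alone (camera adjusted p = 7.13e-24; adjusted p = 0.296 with an estimated correlation). Besides Ibsp and Alpl these included Smpd3 (-1.90), a sphingomyelinase needed for mineralization, and Omd (-1.61). Of the Wnt/β-catenin targets, also called lower by camera, 5 of 16 were lower and 0 higher, 5 and 2 adjusted over the list alone (adjusted p = 0.296 with an estimated correlation). Tcf7 and Wif1 fell by 2.63 and 2.30 on the log2 scale, and Myc by 1.29. Nkd2 had 2 counts in NM-Brdi and 68 in NM-DMSO, a 40.9-fold ratio with a 95% counting interval of 10.9 to 345. Of the BMP and TGF-β pathway, called higher by camera, 5 of 26 genes were higher and 1 lower, 12 and 2 adjusted over the list alone (adjusted p = 0.349 with an estimated correlation), with Smad9 (0.88) among the higher. Osteoblast transcription factors (3 of 15 lower and 0 higher, 5 and 2 adjusted over the list alone) and macrophage and osteoclast markers (1 of 6 lower, 4 adjusted over the list alone) were called lower by camera. Interferon-stimulated genes were called higher with 0 of 21 members called by edgeR, also adjusted over the list alone (8 at an unadjusted p under 0.05, 0 called by DESeq2). The adjusted p of these 3 lists was 0.349, 0.296 and 0.349 with an estimated correlation. Without NM-DMSO replicate 2 the camera calls of osteoblast transcription factors, Wnt/β-catenin targets, interferon-stimulated genes and macrophage markers were lost (adjusted p = 0.25, 0.0759, 0.677 and 0.0853). The first was also lost without NM-Brdi replicate 1 (0.108) and the interferon list without NM-Brdi replicate 2 (0.0721).

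Outside the lists, Panx3, which encodes a channel of osteoblasts and chondrocytes, was 9.47-fold lower in NM-Brdi. C1qtnf3, Agt, Kctd14, Itga10 and Hapln1 were 4.61-fold to 7.18-fold lower. Npr3, the clearance receptor for natriuretic peptides, was 7.89-fold higher, and Ccn5, Met, Elovl7, Sipa1l2, Bdnf, Slc8a1, Alcam, Adgrb2 and Tent5c were 2.65-fold to 4.17-fold higher.

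Altogether 318 genes were called between NM-Brdi and NM-DMSO, 139 higher and 179 lower. The share called higher was 43.7%, and 24.3% in the voom fit with quality weights. It was also smaller whenever a library outside NM-DMSO was left out. The count changed whichever library was left out, also those of Brd and control, which enter only through the shared estimate of the spread. It was 2491 without NM-DMSO replicate 1, 9556 without NM-DMSO replicate 2, 8 and 71 without NM-Brdi replicates 1 and 2, 57 without either Brd library and 39 without either control library. With the 4 libraries of this pair alone, edgeR called 0 genes, against 1463 at an unadjusted p under 0.05, and the DESeq2 Wald test on the 8 libraries called 917. Of 44 called genes that the naming rule takes, Ibsp, Npr3, Panx3, Agt and Itga10 stayed called whichever library was left out. Runx2, Bglap and Spp1 lost the call when any 1 of the 6 libraries outside NM-DMSO was left out, and Sp7 when a Brd library, a control library or NM-Brdi replicate 1 was. Alpl lost it without NM-Brdi replicate 1. Over the fits without 1 library the log2 fold change ranged from -1.212 to -0.802 for Sp7 and from -0.896 to -0.6 for Runx2. It ranged from -2.156 to -1.53 for Bglap, from -0.893 to -0.569 for Spp1 and from -2.97 to -2.414 for Alpl.

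**Figure D3:**
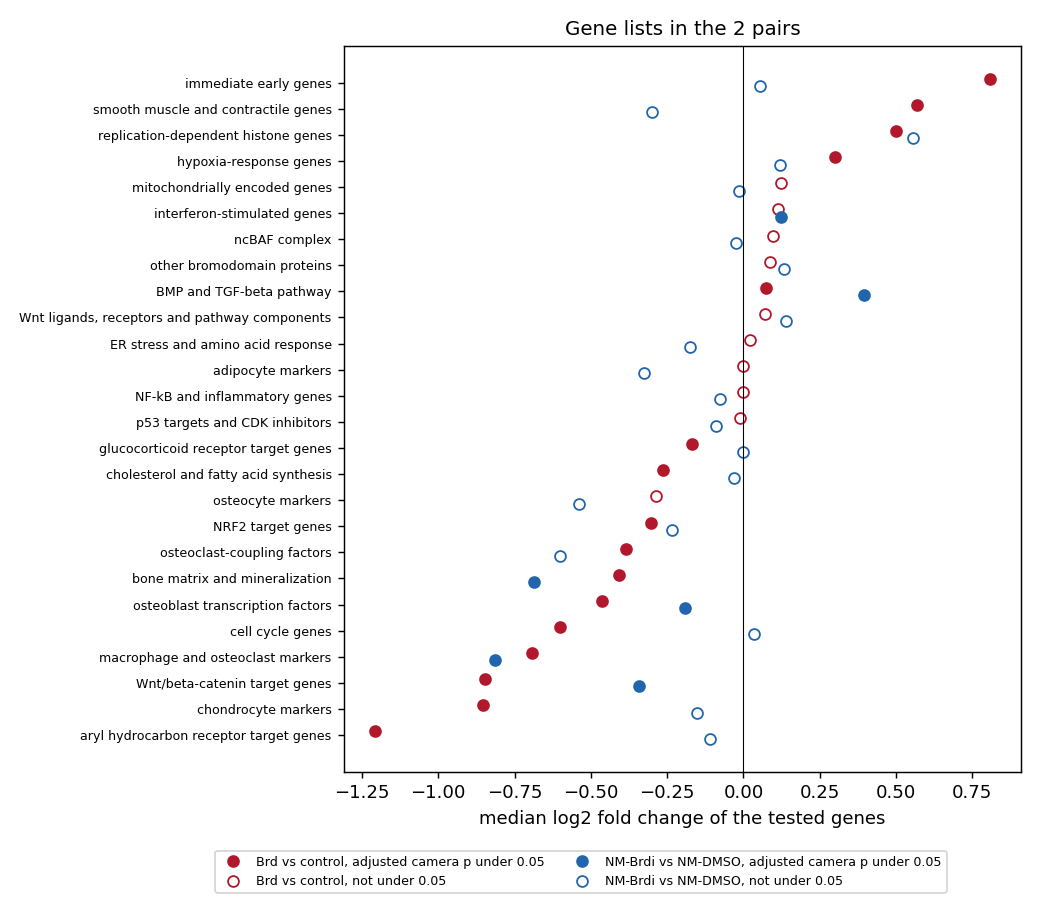
Median log2 fold change of the tested genes of 26 lists in Brd against control (red) and NM-Brdi against NM-DMSO (blue); filled points have an adjusted camera p under 0.05 with the preset correlation. Cell cycle genes had a median of -0.60 in the first pair and 0.04 in the other.

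The effects of the pairs, which share no library, ran in the same direction for most called genes. Across the 17038 genes the log2 fold changes had a Pearson r of 0.454 and a Spearman rho of 0.385; genes are not independent replicates, so no p is attached. Both pairs called 214 genes. Of these, 90 were higher in both (4.3 expected from independent lists) and 120 lower in both (6.2 expected), while 4 were lower in Brd and higher in NM-Brdi and 0 the reverse. The lists come from the same fit with a shared spread per gene, so they are not independent and the expected numbers are a rough guide. Of all tested genes 64% had the same sign in both pairs. Sp7, Runx2, Alpl, Ibsp, Spp1, Lum, Dcn and Tcf7 were among the genes called lower in both. The correlation was 0.292 without NM-DMSO replicate 2, and 0.093 without a filter on low counts, over 28901 genes.

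**Figure D4:**
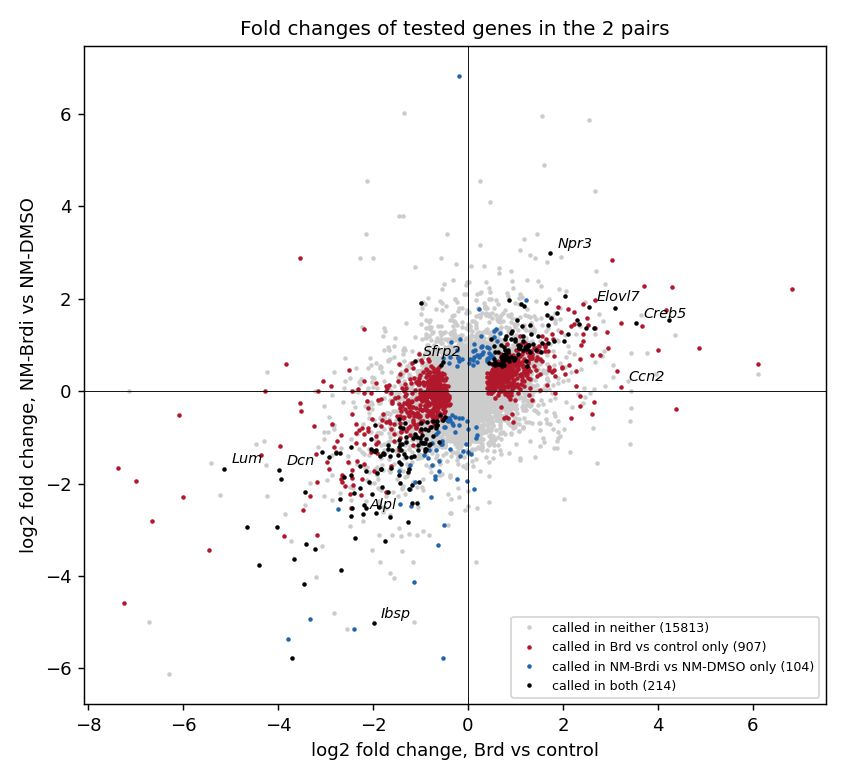
Log2 fold change of each tested gene in Brd against control (x axis) and NM-Brdi against NM-DMSO (y axis); each point is a gene, coloured by the comparison that called it. The 214 genes called in both (black) lie mostly in the quadrants of equal sign.

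The interaction asked which effects differed between the pairs. It called 7 genes (1580 at an unadjusted p under 0.05). Ccn2 was 9.31-fold higher in Brd than in control, and had 46.3 ± 8.31 CPM in NM-Brdi and 43.4 ± 1.32 CPM in NM-DMSO (interaction 3.13, SE 0.24, adjusted p = 0.00793). Lum fell more in the Brd pair than in the NM pair (interaction -3.45, SE 0.27, adjusted p = 0.00793). Ccn3, of the same matricellular family as Ccn2, had an interaction of -2.11, and Sfrp2, a secreted Wnt modulator, one of -1.76. Draxin (-2.89), Gas1 (-1.20) and Cdc42ep3 (1.31) were the others. For Sp7 the interaction was -0.09 (SE 0.20) and for Runx2 0.08 (SE 0.19), neither called. Ibsp (3.05, adjusted p = 0.081), Spp1 (-1.21, adjusted p = 0.0827) and Axin2 (-0.95, adjusted p = 0.159) missed the threshold. Over the fits without 1 library their interaction ranged from 2.502 to 3.911, from -1.39 to -1.056 and from -1.113 to -0.772. Col1a1, Bglap, Alpl and Ctnnb1 were not called either.

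Of the lists, cell cycle genes had a negative interaction in all 30 members (median -0.59), with 0 called by edgeR over all genes and 21 adjusted over the list alone (adjusted p = 0.103 with an estimated correlation). Unadjusted, 22 had a p under 0.05, and DESeq2 called 14. Immediate early genes had a median of 0.74, with 0 called by edgeR (9 at an unadjusted p under 0.05, 2 by DESeq2) and 8 adjusted over the list alone (adjusted p = 0.103 with an estimated correlation). Smooth muscle and contractile genes were positive in 8 of 8, with 0 called by edgeR (5 at an unadjusted p under 0.05, 1 by DESeq2) and 5 adjusted over the list alone (adjusted p = 0.267 with an estimated correlation). The interaction count was 1586 without NM-DMSO replicate 1 and 7480 without NM-DMSO replicate 2. It was 0 in edgeR when any 1 of the other 6 libraries was left out, so that each of the 7 genes lost its call, with 928 to 1120 genes at an unadjusted p under 0.05, and DESeq2 called 300 on all libraries.

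Between control and NM-DMSO, the reference groups of the pairs, glucocorticoid receptor target genes had the largest median difference of the 26 lists. All 17 tested members were called higher in control, and 17 adjusted over the list alone (median log2 fold change 2.38, camera adjusted p = 0.00168 with an estimated correlation). Sgk1, a kinase induced by glucocorticoids, stood at 335 ± 10.0 CPM in control and 19.9 ± 1.29 CPM in NM-DMSO. Fkbp5, a chaperone that feeds back on the receptor, had a log2 fold change of 2.96 (SE 0.12, adjusted p = 4.46e-05). Per1 and Glul had log2 fold changes of 2.32 and 2.38. Hif3a had 425 counts in control and 0 in NM-DMSO, which makes it at least 167-fold higher against a floor of 3 counts over the group. Zbtb16 had 922 counts against 2, a 542-fold ratio with a 95% counting interval of 150 to 4480. The dexamethasone of the osteogenic medium is a glucocorticoid, but no label says which libraries received it.

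Of the 10 genes fixed for every comparison, Ibsp was 13.0-fold higher in control than in NM-DMSO (adjusted p = 0.000667), Axin2 3.27-fold (adjusted p = 0.000565), Alpl 3.14-fold (adjusted p = 0.00177), Spp1 1.90-fold (adjusted p = 0.00449) and Sp7 1.43-fold (adjusted p = 0.0394). Bglap was 2.43-fold lower (adjusted p = 0.0235), and Ctnnb1 1.63-fold higher (adjusted p = 0.00467). Brd9 (log2 fold change -0.03, adjusted p = 0.859), Runx2 (0.29) and Col1a1 (0.13) did not pass the test. Of 15 osteoblast transcription factors 5 were higher and 2 lower, 7 and 2 adjusted over the list alone, and camera did not call the list (adjusted p = 0.132). Sash3 was at least 276-fold higher, with 704 counts against 0. Dpep1 had 1281 counts against 1, a 1510-fold ratio with a 95% counting interval of 270 to 59500. Mettl21e, Ikzf4, Hp, Crispld2, Shroom3 and Adam12 were 27.9-fold to 87.7-fold higher. Kcnj2, Egr2, Lamp5, Tspan7, Sema6a, Sema3c, Rspo3, Ak4, Aldh1a3 and Gas2 were 5.28-fold to 17.1-fold lower.

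Genes of cholesterol and fatty acid synthesis were lower in control, 15 of 25 and 18 adjusted over the list alone (adjusted p = 0.0366 with an estimated correlation), with Msmo1 (-0.92), Sc5d (-0.79) and Dhcr7 (-0.81) among them. Wnt ligands, receptors and components were higher, 16 of 36 against 2 lower, 20 and 2 adjusted over the list alone (adjusted p = 0.0837 with an estimated correlation). Lrp5, a Wnt co-receptor, rose by 2.09 on the log2 scale and Fzd1 by 1.64. The Wnt/β-catenin target genes, which include Axin2, did not rise as a group (median log2 fold change -0.30). Of 16 targets 3 were higher and 4 lower, 4 and 7 adjusted over the list alone, and camera did not call the list (adjusted p = 0.519). Immediate early genes were lower in 7 of 13 and higher in 1, 7 and 2 adjusted over the list alone (adjusted p = 0.0837 with an estimated correlation). The BMP and TGF-β pathway (11 of 26 higher and 2 lower, 12 and 3 adjusted over the list alone), chondrocyte markers (4 of 8 higher, 5 adjusted over the list alone) and bone matrix genes (9 of 26 higher and 4 lower, 9 and 4 adjusted over the list alone) were called higher by camera. For these the adjusted p was 0.327, 0.143 and 0.69 with an estimated correlation. Without NM-DMSO replicate 2 the camera calls of immediate early, chondrocyte and bone matrix genes were lost (adjusted p = 0.0722, 0.0772 and 0.152), the last also with a correction for transcript length (0.054). In every called list of the 4 comparisons the median, the mean and the test had the same sign. In lists not called they differed in places, as for Wnt ligands, receptors and components in Brd against control (median 0.07, mean -0.12).

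Altogether 3988 genes were called, 2037 higher and 1951 lower. The split was 51.1% higher, and 39.0% with a correction for transcript length, which moved the median of all genes to -0.105. The count was 6071 without NM-DMSO replicate 1, 11204 without NM-DMSO replicate 2, 555 and 568 without control replicates 1 and 2, 1476 to 1592 without a Brd or NM-Brdi library, and 382 in a fit of the 4 libraries alone. Of these calls 53.9%, 49.8%, 81.6% and 80.1%, 66.7% to 67.9%, and 83.5% were higher, in the same order. Sp7 and Bglap lost the call when any 1 Brd or control library was left out, Ctnnb1 without either control library, and Spp1 without control replicate 1. Over the fits without 1 library the log2 fold change ranged from 0.459 to 0.578 for Sp7 and from -1.527 to -0.988 for Bglap. It ranged from 0.613 to 0.803 for Ctnnb1 and from 0.773 to 1.091 for Spp1. Runx2 (log2 fold change 0.29) and Col1a1 (0.13), not called, ranged from 0.183 to 0.411 and from 0.054 to 0.22 over these fits. Both changed sign with the length correction (-0.071 and -0.209).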

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

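The correction for transcript length and the test of length on NM-DMSO replicate 1 were chosen after the trend was seen, and so was the form for the whole cause; the other tests of this part were written before their results. The effects of the pairs differed by the interaction test in 7 genes. The interaction log2 fold change was -3.45 for Lum, -2.89 for Draxin, -2.11 for Ccn3, -1.76 for Sfrp2, -1.20 for Gas1, 1.31 for Cdc42ep3 and 3.13 for Ccn2. Each of the 7 lost its call when any 1 Brd, control or NM-Brdi library was left out, and then edgeR called 0 genes (928 to 1120 at an unadjusted p under 0.05).

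By camera with the preset correlation, 7 lists differed as well, none of them with an estimated correlation (4 at an unadjusted p under 0.05). Their median interaction was -0.59 for cell cycle genes, 0.74 for immediate early genes, 0.79 for smooth muscle and contractile genes and 0.34 for bone matrix and mineralization. It was -0.61 for chondrocyte markers, -0.21 for cholesterol and fatty acid synthesis and 0.24 for ER stress and amino acid response. The adjusted p with an estimated correlation was 0.103, 0.103, 0.267, 0.48, 0.287, 0.267 and 0.586 in this order. Leaving out 1 library ended the preset-correlation call of 3 of the 7. The adjusted p reached 0.229 for chondrocyte markers and 0.107 for cholesterol and fatty acid synthesis, both without NM-DMSO replicate 2, and 0.891 for ER stress without NM-DMSO replicate 1. A correction for transcript length also ended the calls of cholesterol and fatty acid synthesis (adjusted p = 0.0593) and of ER stress (0.0523).

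Cell cycle genes were lower in the Brd pair (median -0.60) and not in the NM pair (median 0.04). The spread of the NM-DMSO libraries is argued against, since the median interaction was -0.73 without replicate 1 and -0.52 without replicate 2. A trend with transcript length is argued against too, since the median was -0.54 with that trend removed. The call of the list was lost with an estimated correlation (adjusted p = 0.103). What the groups received beyond their titles stays open and untested.

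NM-DMSO replicate 1 stood apart from replicate 2. For RNA of other cells, only markers of blood, macrophage, endothelial, epithelial and skeletal muscle cells were summed, so other cell types stay open. The blood genes were not in the lists fixed beforehand. These 39 marker genes summed to 136.4 CPM in replicate 1 and 89.0 CPM in replicate 2. The difference of 47.5 CPM lay below the bound set for it, which argues against a large share of RNA from these cells as the cause. However, 4 globin genes among them had 402 counts (19.95 CPM) against 4 counts in replicate 2 and leave a trace of blood RNA open. A library of another group under this label is argued against, since replicate 1 lay 0.022 of the way from replicate 2 to control in glucocorticoid genes and -0.072 of the way to NM-Brdi in the genes called between Brd and control. Transcript length as the whole cause is argued against. Of the 16628 genes with an annotated length, 551 were over 2-fold apart, and 374 of these stayed so with the trend removed. In all 427 genes were then over 2-fold apart, 53 of them new, against at most 1 in the other groups. This form of the test, with its bound, was added when the total was already known. Whether length is part of the cause cannot be told apart from other sources: the first form of the test asked for rho beyond 0.3 and over 50% of the genes removed, and found a rho of -0.348 (at most 0.109 in size in the other groups) but 177 of 551 (32.1%) removed, which decides neither way.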

How the results depend on the processing

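The length correction and the voom fit were chosen after seeing the data. DESeq2 size factors moved no count by over 1.5 times, and every gene called between Brd and control, in NM-Brdi against NM-DMSO or by the interaction kept its sign in every alternative. Between control and NM-DMSO 34 called genes changed sign with the length correction. Of the values of named genes under the alternatives, 3422 kept direction and side of the threshold, 770 lost the call, 210 gained one and 10 reversed.

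Without a filter on low counts 1848 genes were called in Brd against control, 2453 in NM-Brdi against NM-DMSO, 608 by the interaction and 6274 in control against NM-DMSO, and the correlation of the pairs was 0.093; more genes, 28901, were then tested. Leaving out 1 library gave 34 to 5546, 8 to 9556, 0 (928 to 1120 at an unadjusted p under 0.05) to 7480 and 555 to 11204 calls by edgeR in the same order, 3 to 12 lists in NM-Brdi against NM-DMSO, and a correlation of 0.292 to 0.477. It gave 4 to 10 lists for the interaction and for control against NM-DMSO. Fits of the 4 libraries of a comparison called 6412, 0 (1463 at an unadjusted p under 0.05 in edgeR) and 382 genes for the comparisons other than the interaction. The voom fit with quality weights called 5876, 144, 154 and 2597 genes. The length correction called 511 genes in NM-Brdi against NM-DMSO and 83 by the interaction, and the DESeq2 Wald test 917 and 300. With an estimated correlation 0, 0, 0 and 2 lists were called, with 9, 3, 4 and 5 at an unadjusted p under 0.05. Apart from the smaller or larger sets of genes and libraries, the cause was not tested.

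Replicate numbers did not clearly pair the samples. Deviations of libraries with the same number correlated at -0.003 to 0.038 between most groups. Between NM-Brdi and NM-DMSO the correlation was 0.152, so a pairing by number stays open there. With the replicate block 970, 188, 5 and 3753 genes and 16, 8, 8 and 7 lists were called.

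The reversed values of named genes were all of genes not called in that comparison. Over the fits without 1 library Col1a1 in Brd against control ranged from -0.126 to 0.014 (without control replicate 2), and Brd9 in control against NM-DMSO from -0.073 to 0.018 (without control replicate 2). Ctnnb1 in NM-Brdi against NM-DMSO ranged from -0.069 (without NM-DMSO replicate 1) to 0.115, with -0.008 without NM-Brdi replicate 2, and was -0.031 with the length correction. The interaction ranged from -0.275 to 0.133 (without NM-Brdi replicate 2) for Sp7. For Runx2 it ranged from -0.060 (without NM-Brdi replicate 1) to 0.233, with -0.039 without NM-DMSO replicate 2. With the length correction Runx2 and Col1a1 stood at -0.071 and -0.209 in control against NM-DMSO. The cause was not tested. Some genes had few counts, such as Bglap with a mean of 1.86 CPM in Brd, and whether depth limited their tests was not examined.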

Other observations

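The tests of this part were all chosen after the data were seen, and the tests without the genes that prompted a list were added after the values of the whole lists were known. Targets of YAP and TAZ, coactivators that respond to cell tension and density, include Ccn2 and Ankrd1, both called higher in Brd than in control. Of 21 such genes 4 were called higher in Brd than in control and 1 lower (median log2 fold change 0.29; camera p = 2.09e-05, or p = 0.1 with an estimated correlation). In NM-Brdi 3 were higher and 0 lower (median 0.29; camera p = 0.000725, or p = 0.164 with an estimated correlation). Ccn2 itself was not called in NM-Brdi (log2 fold change 0.09) and was the 1 gene of the list called by the interaction (3.13), and Ankrd1 was not called in NM-Brdi either (0.56). Without Ccn2 and Ankrd1, which prompted the list, it was not called in Brd (2 of 19 higher and 1 lower; camera p = 0.0728, or p = 0.413 with an estimated correlation) and was called higher in NM-Brdi only with the preset correlation (camera p = 0.00131, or p = 0.175 with an estimated one). A response of these genes shared by the pairs therefore stays undecided.

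Small leucine-rich proteoglycans, the family of Lum and Dcn, were tested in both pairs. Of 11 genes 4 were called lower in Brd (median -0.67; camera p = 1.3e-15, or p = 0.0101 with an estimated correlation) and 5 in NM-Brdi (median -0.73; camera p = 6.16e-09, or p = 0.028 with an estimated correlation), and 0 were higher in either. Lum was the 1 gene of the list called by the interaction (-3.45), with a larger decrease in the Brd pair. Without Lum and Dcn, which prompted the list, 2 of 9 were lower in Brd (camera p = 0.00151, or p = 0.11 with an estimated correlation) and 3 in NM-Brdi (camera p = 0.000217, or p = 0.0763 with an estimated correlation). A shared response of the other members may be followed up, but it rests on the preset correlation, and Dcn, Bgn, Ogn and Omd are also in the list of bone matrix.

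The glucocorticoid targets that were higher in control than in NM-DMSO were also higher in Brd than in NM-Brdi, in 16 of 17 genes called (median log2 fold change 2.11). These comparisons share no library. Yet the interaction called 0 of the 17 (median 0.03), so the outcome largely followed from the earlier comparisons and adds little. A glucocorticoid difference between the libraries without and with the prefix NM, such as dexamethasone in the medium, would give this pattern. The labels do not state it, and other differences between the cultures were not tested.

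Transcripts of 4 adult globin genes (Hbb-bs, Hbb-bt, Hba-a1 and Hba-a2) were found in NM-DMSO replicate 1 with 402 counts, or 19.95 CPM. The other libraries had 0 to 10 counts. These genes are near-identical copies in pairs, so only their sum is given.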
